A study of Mus musculus with 12 samples.

How the data were processed

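Messenger RNA with a poly(A) tail was sequenced from the gastrocnemius of male wild-type mice of the inbred strains C57BL/6 and BALB/c. Per the labels' protocols, the sciatic nerve of the right leg was cut and its ends were turned away and sutured to muscle, and the muscle was taken 2 weeks after surgery. The labels call the left leg healthy; the protocol also speaks of a sham operation, and no label says whether the left legs had one. Groups were taken from the labels as strain and leg, 4 groups of 3 libraries. The numbers of the titles name the libraries here. In the BALB/c table the last column code of each leg differs from its title number. Columns were matched through the code in each sample's description.

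The authors deposited RPKM values (reads scaled by the length of the listed transcript and by the reads of the library), in 1 table per strain; the column names say FPKM while the command recorded in the file headers asks for RPKM. Per the file headers, HOMER counted reads of both strands in exons, kept 1 transcript per gene and used its mm9 annotation. The submitters' processing notes name HISAT2, HOMER and DESeq2 without versions or roles, and the builds GRCm38 and mm10. Of 24551 genes matched by symbol and chromosome to a GRCm38 table, 2722 overlapped their GRCm38 position, so positions are given in mm9 as the files list them. Which build the reads were aligned to is not given in the sources used here beyond those names. The 2 tables list 25094 genes each, 23630 of them with the same transcript in both and 1464 with another one. Every sample column was used. The tables were normalized separately, so tests were made within a table and levels were not tested across them. Because strand was not used, overlapping and antisense genes share reads, and near-identical copies such as Amd1 and Amd2 or the haemoglobin genes cannot be separated.

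Multiplying each RPKM value by transcript length and a scaling total gave whole reads within a tolerance of 0.1 read for 99.8% to 99.9% of the values of each library. The scaling totals were 18132600 to 19282900 reads, and 14826900 to 17323400 reads lay in listed genes. The lower limit of detection was set at 3 reads per library. A Poisson ratio for a gene with few reads carries an exact 95% interval, and floors and intervals cover counting error only.

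RPKM values were transformed to log2(RPKM + 0.5), a scale that understates the change of genes with low values. Genes with a mean of at least 0.1 RPKM over the 6 libraries of a table were tested for right against left with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05. The difference between the strains was the contrast of the BALB/c change minus the C57BL/6 change in 1 fit over all 12 libraries, with genes tested in both tables. Overlap of calls was tested with a one-sided Fisher's exact test per direction. Gene lists, 18 of pathways and 13 of cell types and tissue handling, were tested two-sided with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists with at least 3 tested members. Camera compares a list with all other tested genes, so a list can be lower than the other genes while few of its members fell. Chrna7 was compared by exact two-sided permutation tests of the library values.

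The designs, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Per strain the rule took Chrna7, 14 fixed genes, the 5 largest rises and the 5 largest falls among called genes with a mean of at least 1 RPKM and no overlap between the legs, and up to 2 called members per list and direction with the largest change, or the largest member where none was called. For the difference between strains it took the 5 largest in each direction. Some genes that the rule takes are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

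Reads were simulated with 200 changed genes, each with a mean of at least 1 RPKM in the left legs. All genes of a strain had the same spread, the median of genes with many reads in its left libraries. No shift of the median gene was simulated, so the rates do not carry over to noisier or lower genes or to the deposited values. In this setting the C57BL/6 test recovered 74.6% of changes of 1.5-fold, 97.0% of 2-fold and 100% of 4-fold, with 9 false calls among 13811 genes. The BALB/c test recovered 17.9%, 94.0% and 100%, with 15 false calls among 14498 genes. The test of the difference between the strains recovered 13.4%, 76.1% and 100%, with 4 false calls among 13430 genes.

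The alternatives were pseudocounts of 0.1 and 1, no filter and a filter of 1 RPKM, rescaling by median-of-ratios factors, to a common sum (TPM) or by quantiles, the replicate number as a block, eBayes without a trend, a spread shared over all 12 libraries, a minimum absolute log2 change of 1, an estimated inter-gene correlation and leaving out each library in turn. Added after the data were seen were limma-voom on the recovered reads, with and without median-of-ratios factors, the overlap between the strains with those factors, leaving out both BALB/c libraries numbered 2, and 2 further gene lists. Tables were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.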

Results

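RNA was sequenced from the gastrocnemius, a calf muscle, 2 weeks after the right sciatic nerve had been cut, in male mice of the strains C57BL/6 and BALB/c. The left leg of the same strain served as the comparison, and each of the 4 groups held 3 libraries. The libraries were scaled by totals of 18132600 to 19282900 reads. Means are in RPKM with the SD over 3 libraries. Changes are right minus left on the log2(RPKM + 0.5) scale, with their SE where an error is given. Adjusted p-values are from limma with Benjamini-Hochberg adjustment. The median tested gene was 0.52 higher in the right legs of C57BL/6 and 0.38 higher in those of BALB/c, and relative changes have that median subtracted. The labels do not say that the libraries of a group came from separate mice, so the p-values measure only the spread between these samples, which may be technical. Positions are in mm9.

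The series names the α7 nicotinic acetylcholine receptor, encoded by Chrna7 (NM_007390, chromosome 7, 70243578 to 70357412), as the protein of interest in denervated muscle. In C57BL/6, Chrna7 had 1, 0 and 0 reads in the left and 1, 3 and 1 reads in the right legs, or 0.00833 ± 0.0144 and 0.0420 ± 0.0294 RPKM (SD, n = 3 libraries each). In BALB/c it had 1, 3 and 0 reads in the left and 1, 0 and 0 reads in the right legs, or 0.0353 ± 0.0408 and 0.00833 ± 0.0144 RPKM. A count of 3 reads corresponded to 0.0748 to 0.0796 RPKM, and no library had more reads than that. The ratio of right to left was 4.90 in C57BL/6 (exact 95% interval 0.548 to 232) and 0.225 in BALB/c (0.00456 to 2.27). Exact two-sided permutation tests gave p = 0.3 and p = 0.4, where 0.1 is the smallest value that 3 against 3 libraries allow. Over both strains the exact permutation p was 1 (400 arrangements, smallest possible 0.005). Chrna7 lay below the filter for the test across genes, and a difference between the legs was not detectable at this depth.

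In C57BL/6, the comparison of the right with the left leg asked which transcripts changed after the nerve was cut. Subunits of the acetylcholine receptor of fetal and denervated muscle rose the most among the nicotinic receptor genes. Chrng, the gamma subunit of the fetal receptor (NM_009604, chromosome 1, 89102386 to 89108410), rose from 0.0650 ± 0.0422 to 154 ± 4.78 RPKM (log2 change 8.10 ± 0.08, relative 7.57, adjusted p = 1.0e-08). Chrna1, the alpha subunit of the muscle receptor (NM_007389, chromosome 2, 73401338 to 73418395), rose from 1.66 ± 0.981 to 248 ± 20.5 RPKM (log2 change 6.98 ± 0.36, relative 6.46, adjusted p = 4.4e-06). Chrnd, the delta subunit, rose from 0.329 ± 0.227 to 211 ± 17.9 RPKM (relative log2 change 7.51). Chrne, which replaces the gamma subunit in adult muscle, was not called, with 9.74 ± 5.43 RPKM in the left and 11.6 ± 2.81 RPKM in the right legs (log2 change 0.41 ± 0.46, relative -0.11, adjusted p = 0.445). Musk, the receptor kinase that organizes the synapse, rose from 2.03 ± 0.204 to 14.5 ± 2.86 RPKM (relative log2 change 2.03). Ache, acetylcholinesterase, fell from 12.8 ± 2.66 to 3.68 ± 1.12 RPKM (relative log2 change -2.21).

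Of the 18 measured genes of the muscle nicotinic receptor and neuromuscular junction list, 14 rose and 1 fell in C57BL/6. The list as a whole did not pass camera as deposited (adjusted p = 0.0708). After median-of-ratios rescaling 9 rose and 2 fell, and the list passed as higher (adjusted p = 0.00598; adjusted p = 0.407 with an estimated correlation). Of 11 listed other nicotinic subunits 3 were measured, of which 2 rose and 1 fell (camera adjusted p = 0.629). Adjusted over the list alone, the counts of both lists were the same. Chrna9 rose to 1.38 ± 0.813 RPKM in the right legs (relative log2 change 1.02) and Chrnb2 to 0.488 ± 0.108 RPKM (relative log2 change 0.39). Chrna10 fell from 4.28 ± 0.906 to 2.38 ± 0.317 RPKM (relative log2 change -1.24).

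Myogenic and denervation-responsive regulators rose together in C57BL/6. Of 20 measured, 17 rose and 2 fell, also when adjusted over the list alone. Camera placed the list higher than other genes (adjusted p = 0.00403; adjusted p = 0.166 with an estimated correlation). Myog, the muscle transcription factor myogenin (NM_031189, chromosome 1, 136186581 to 136189125), rose from 3.17 ± 1.38 to 183 ± 92.4 RPKM (log2 change 5.57 ± 0.41, relative 5.04, adjusted p = 2.0e-05). Gadd45a, a growth-arrest gene, rose from 11.4 ± 3.15 to 799 ± 25.9 RPKM (relative log2 change 5.58). Runx1, a transcription factor, rose from 0.234 ± 0.0463 to 33.3 ± 3.27 RPKM (relative log2 change 5.0). Ncam1, a cell adhesion molecule, rose from 0.805 ± 0.402 to 42.9 ± 2.40 RPKM (relative log2 change 4.58). Myh3, embryonic myosin, rose from 0.981 ± 0.0878 to 63.5 ± 19.1 RPKM (relative log2 change 4.86).

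The largest rise in C57BL/6 under the rule for named genes was that of Sln, sarcolipin, an inhibitor of the calcium pump of the sarcoplasmic reticulum (NM_025540, chromosome 9, 53698058 to 53701656). It rose from 0.992 ± 0.654 to 7018 ± 2494 RPKM (log2 change 12.23 ± 0.34, relative 11.71, adjusted p = 5.1e-07). The keratin Krt18 (NM_010664, chromosome 15, 101858647 to 101862457) rose from 0.432 ± 0.143 to 674 ± 35.8 RPKM (log2 change 9.51 ± 0.12, relative 8.99, adjusted p = 3.1e-08) and Krt8 from 0.137 ± 0.0896 to 185 ± 29.6 RPKM (relative log2 change 7.66). Aldh3a1, an aldehyde dehydrogenase, rose from 0.157 ± 0.0973 to 418 ± 152 RPKM (relative log2 change 8.74). Rrad, a Ras-related GTPase, rose from 1.06 ± 0.0765 to 437 ± 64.1 RPKM (relative log2 change 7.60). The largest falls were those of Amd1 and Amd2, copies of the polyamine enzyme S-adenosylmethionine decarboxylase that share their reads. Amd1 fell from 155 ± 17.5 to 3.62 ± 1.54 RPKM (relative log2 change -5.82). Dhrs7c, a dehydrogenase of the sarcoplasmic reticulum (NM_001013013, chromosome 11, 67611773 to 67629504), fell from 185 ± 22.0 to 5.44 ± 2.27 RPKM (log2 change -5.03 ± 0.25, relative -5.55, adjusted p = 3.8e-06). Mybpc2, fast myosin-binding protein C, fell from 1827 ± 109 to 60.2 ± 25.6 RPKM (relative log2 change -5.52). Fam71e1 (relative log2 change -5.40) overlaps Mybpc2, and their reads cannot be told apart without strand.

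**Figure D1:**
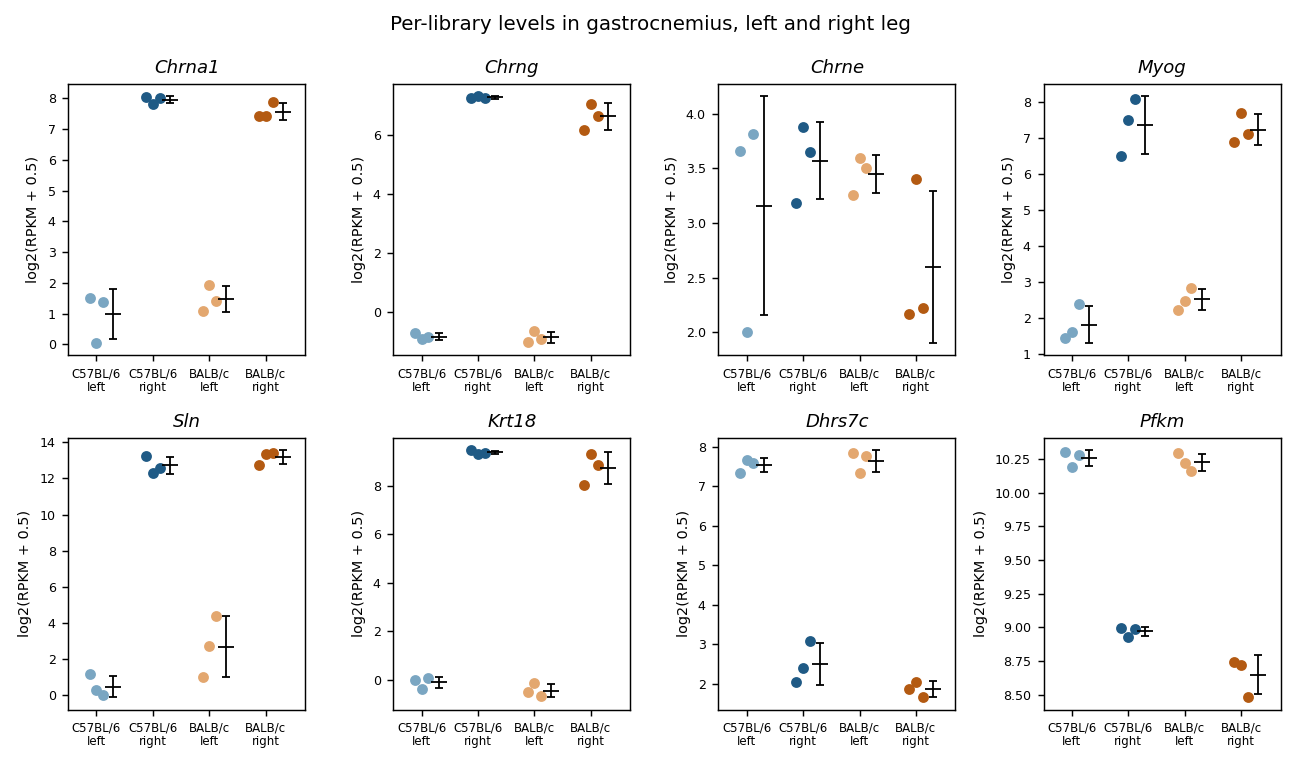
Each panel shows 1 gene, with log2(RPKM + 0.5) of each library on the vertical axis and the 4 groups (left and right leg of C57BL/6 and BALB/c) on the horizontal axis, where points are libraries and bars the mean and SD of 3 libraries. Chrna1, Chrng, Myog, Sln and Krt18 were higher and Dhrs7c and Pfkm lower in the right legs of both strains, while Chrne was not called in either strain as deposited and was lower in BALB/c after median-of-ratios rescaling.

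Glycolysis and glycogen genes fell in the right legs of C57BL/6. Of 23 measured, 20 fell and 2 rose (21 and 2 when adjusted over the list alone). The camera adjusted p was 3.5e-25, with an adjusted p of 0.0374 with an estimated correlation, or of 0.145 when the values were also rescaled by median-of-ratios factors. Pfkm, muscle phosphofructokinase (NM_001163488, chromosome 15, 97923020 to 97962878), which overlaps Senp1, fell from 1226 ± 48.2 to 501 ± 12.3 RPKM (log2 change -1.29 ± 0.08, relative -1.81, adjusted p = 9.8e-06). Pfkfb3, a regulator of glycolysis, fell from 188 ± 8.86 to 8.68 ± 0.607 RPKM (relative log2 change -4.88). Gpd1, glycerol-3-phosphate dehydrogenase, fell from 339.7 ± 6.93 to 38.6 ± 4.92 RPKM (relative log2 change -3.65).

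Of 49 nuclear genes of oxidative phosphorylation, 21 rose and 1 fell in C57BL/6 as deposited (19 and 1 when adjusted over the list alone), and 1 rose and 39 fell after median-of-ratios rescaling. The list was lower than other genes after rescaling (camera adjusted p = 6.9e-08; adjusted p = 0.564 with an estimated correlation) but not as deposited (0.158). Its adjusted p was 0.0303 without C57BL/6 left library 1 and 0.0406 without right library 2. Ndufb7, a complex I subunit, rose from 265 ± 34.3 to 555 ± 54.6 RPKM (relative log2 change 0.54). Cox7a1, a muscle subunit of complex IV, fell from 502 ± 59.3 to 356 ± 57.4 RPKM (log2 change -0.50 ± 0.14, relative -1.02, adjusted p = 0.0132), which was 0.290 with a spread shared over all 12 libraries. Of 41 genes of the citrate cycle, fatty acid oxidation and their regulators, 19 rose and 5 fell as deposited, also when adjusted over the list alone, and 4 rose and 23 fell after median-of-ratios rescaling. Their camera adjusted p was 0.0504 as deposited, 2.5e-04 after rescaling, 0.0494 with a pseudocount of 0.1 and 0.0339 with the filter of 1 RPKM. The rescaled call was lost with an estimated correlation (adjusted p = 0.568). The deposited values gave 0.0280 without C57BL/6 left library 1, 0.0104 without right library 2 and 0.0394 without right library 3. Without right library 2, 8 of these genes fell. Idh3a, an isocitrate dehydrogenase subunit, fell from 191 ± 5.49 to 102 ± 7.09 RPKM (relative log2 change -1.43). Ppargc1a, a coactivator of mitochondrial genes, was not called, with 2.30 ± 0.283 RPKM in the left and 1.78 ± 0.290 RPKM in the right legs (log2 change -0.30 ± 0.13, relative -0.82, adjusted p = 0.0670). Its adjusted p was 7.3e-04 after median-of-ratios rescaling, 0.0326 with limma-voom and 0.0415 without C57BL/6 right library 2.

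Sarcomere genes of fast and slow fibres went in different directions in C57BL/6. Of 16 genes of the fast fibre sarcomere, 13 fell and 2 rose. The list was lower than other genes (camera adjusted p = 2.8e-13; adjusted p = 0.0374 with an estimated correlation, 0.262 when also rescaled by median-of-ratios factors). The 2 that rose were the fast myosins of type 2A and type 2X fibres. Myh2 rose from 81.5 ± 25.4 to 1115 ± 308 RPKM (relative log2 change 3.25) and Myh1 from 161 ± 79.1 to 1133 ± 179.9 RPKM (relative log2 change 2.39). All 15 genes of the slow fibre sarcomere rose (camera adjusted p = 0.00453; adjusted p = 0.680 with an estimated correlation). Csrp3, a Z-disc protein (NM_001198841, chromosome 7, 56085768 to 56103421), rose from 7.02 ± 4.92 to 1546 ± 527 RPKM (log2 change 7.82 ± 0.44, relative 7.30, adjusted p = 6.3e-06). Tnnt1, slow troponin T (NM_001277904, chromosome 7, 4456172 to 4467577), rose from 4.33 ± 3.22 to 597 ± 193 RPKM (relative log2 change 6.61). Of 26 genes of excitation-contraction coupling and ion channels, 9 rose and 11 fell, and 5 rose and 18 fell after median-of-ratios rescaling. That list was lower than other genes (camera adjusted p = 1.1e-05; adjusted p = 0.161 with an estimated correlation). Jph2, which joins the plasma membrane to the sarcoplasmic reticulum, fell from 233 ± 11.3 to 62.8 ± 4.11 RPKM (relative log2 change -2.41). The counts of these 3 lists were the same when adjusted over the list alone.

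Proteasome subunits rose in C57BL/6, and the ubiquitin ligases of muscle atrophy depended on the scaling. Of 32 proteasome subunits 31 rose, and 24 rose and 1 fell after median-of-ratios rescaling (camera adjusted p = 7.5e-05; adjusted p = 0.825 with an estimated correlation). Psmd11 rose from 27.0 ± 0.942 to 88.9 ± 4.31 RPKM (relative log2 change 1.18). Of 26 autophagy and lysosome genes 23 rose and 1 fell, and 9 rose and 6 fell after rescaling. Map1lc3a, an autophagosome protein, rose from 169 ± 16.6 to 1167 ± 102 RPKM (relative log2 change 2.26). The autophagy list had a camera adjusted p of 0.0442, and an adjusted p of 0.285 with an estimated correlation. It was 0.415 after rescaling, 0.127 with the filter of 1 RPKM, 0.0523 without C57BL/6 left library 3 and 0.0643 without right library 1. Of 17 atrophy ubiquitin ligases, 10 rose and 2 fell as deposited, and 2 rose and 10 fell after rescaling. Their camera adjusted p was 0.589 as deposited and 0.0335, lower than other genes, after rescaling (adjusted p = 0.407 with an estimated correlation). Trim63, the ligase MuRF1 (NM_001039048, chromosome 4, 133871035 to 133885544), had 71.7 ± 1.83 RPKM in the left and 91.6 ± 6.27 RPKM in the right legs. Its log2 change by limma was 0.35 ± 0.07 as deposited (adjusted p = 0.00350) and -0.37 after rescaling (adjusted p = 0.00504). Fbxo32, the ligase atrogin-1, was not called, with 21.8 ± 5.94 RPKM in the left and 30.7 ± 3.81 RPKM in the right legs (log2 change 0.51 ± 0.20, relative -0.01, adjusted p = 0.0527). Its adjusted p was 0.0272 without C57BL/6 left library 1, 0.0418 with the filter of 1 RPKM and 0.0394 with limma-voom. Mdm2 rose from 14.4 ± 1.81 to 49.6 ± 5.79 RPKM (relative log2 change 1.23), and Asb2 fell from 193 ± 31.2 to 53.1 ± 11.2 RPKM (relative log2 change -2.39). Adjusted over the list alone, the counts of the proteasome, autophagy and ligase lists were the same.

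Extracellular matrix genes and macrophage markers rose in C57BL/6. Of 33 matrix genes 28 rose (29 when adjusted over the list alone), and 21 rose and 1 fell after median-of-ratios rescaling. Postn, periostin, rose from 0.523 ± 0.127 to 40.9 ± 24.3 RPKM (relative log2 change 4.61). Timp1, a metalloproteinase inhibitor, rose from 0.308 ± 0.0742 to 27.9 ± 6.17 RPKM (relative log2 change 4.59). The matrix list had a camera adjusted p of 0.0347, and an adjusted p of 0.825 with an estimated correlation. The matrix value was 0.0957 with the filter of 1 RPKM, 0.0829 without C57BL/6 left library 3 and 0.0789 without right library 3. All 17 macrophage and monocyte markers rose (camera adjusted p = 0.0151; adjusted p = 0.825 with an estimated correlation, 0.0704 with the filter of 1 RPKM). Among them, Cd68 rose from 0.415 ± 0.163 to 20.8 ± 5.90 RPKM (relative log2 change 4.0) and C1qa from 2.10 ± 0.362 to 26.7 ± 11.7 RPKM (relative log2 change 2.78). Of 14 markers of fibro-adipogenic progenitors and fibroblasts 12 rose, and 6 after rescaling (camera adjusted p = 0.268). Of 10 tendon and cartilage markers 6 rose, and 3 after rescaling, without C57BL/6 left library 1 or without left library 3 (camera adjusted p = 0.629). Scx, a tendon transcription factor that overlaps Bop1, rose from 3.92 ± 0.0789 to 98.6 ± 25.8 RPKM (relative log2 change 3.93). The counts of these 3 marker lists were the same when adjusted over the list alone.

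Endothelial markers did not rise in C57BL/6. Of 14 measured, 4 fell and 0 rose (0 fell when adjusted over the list alone), and 13 fell after median-of-ratios rescaling. The list was lower than other genes (camera adjusted p = 5.7e-04; adjusted p = 0.680 with an estimated correlation). Kdr, a receptor of vascular endothelial growth factor, fell from 3.58 ± 0.372 to 2.45 ± 0.437 RPKM (log2 change -0.48 ± 0.13, relative -1.0, adjusted p = 0.0132), which was 0.130 with a spread shared over all 12 libraries. Without C57BL/6 left library 2, left library 3 or right library 1, 2 endothelial markers fell. Of 15 Schwann cell markers 3 rose and 0 fell (camera adjusted p = 0.232), and 7 rose without left library 1. Of 10 adipocyte markers 1 rose and 1 fell (camera adjusted p = 0.210). Of 7 erythroid genes 0 were called by limma (camera adjusted p = 0.268), and Hbb-b1 had 54.7 ± 17.2 RPKM in the left and 70.7 ± 7.62 RPKM in the right legs (log2 change 0.42 ± 0.23, relative -0.11, adjusted p = 0.146). Adjusted over the list alone, the Schwann cell, adipocyte and erythroid counts were the same.

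Of 11 polyamine genes 5 rose and 3 fell in C57BL/6, also when adjusted over the list alone, and 2 rose and 5 fell after median-of-ratios rescaling. The polyamine list was lower than other genes with a camera adjusted p of 0.0444 (adjusted p = 0.296 with an estimated correlation). It was 0.0793 after rescaling, 0.0579 without C57BL/6 left library 1 and 0.0523 without left library 3. In all, 14551 genes were tested in C57BL/6. As deposited 9258 rose and 1246 fell (88.1% of the calls rose), against 4106 and 3840 after median-of-ratios rescaling (51.7% rose). Changes of at least 2-fold were called for 3289 genes that rose and 416 that fell. The deposited values of the legs did not overlap for 75.7% of the tested genes, where chance gives 10% without a shift between the legs. The median gene was shifted by 0.52, which can separate the legs by itself. The excess over 10% is therefore no measure of how many genes changed. Of the 31 lists 6 were higher and 6 lower than other genes with the preset correlation, and 2, glycolysis and the fast sarcomere, passed with an estimated correlation. The 10 most abundant genes held 36.5% to 38.3% of the reads of the left and 17.6% to 18.1% of those of the right libraries.

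**Figure D2:**
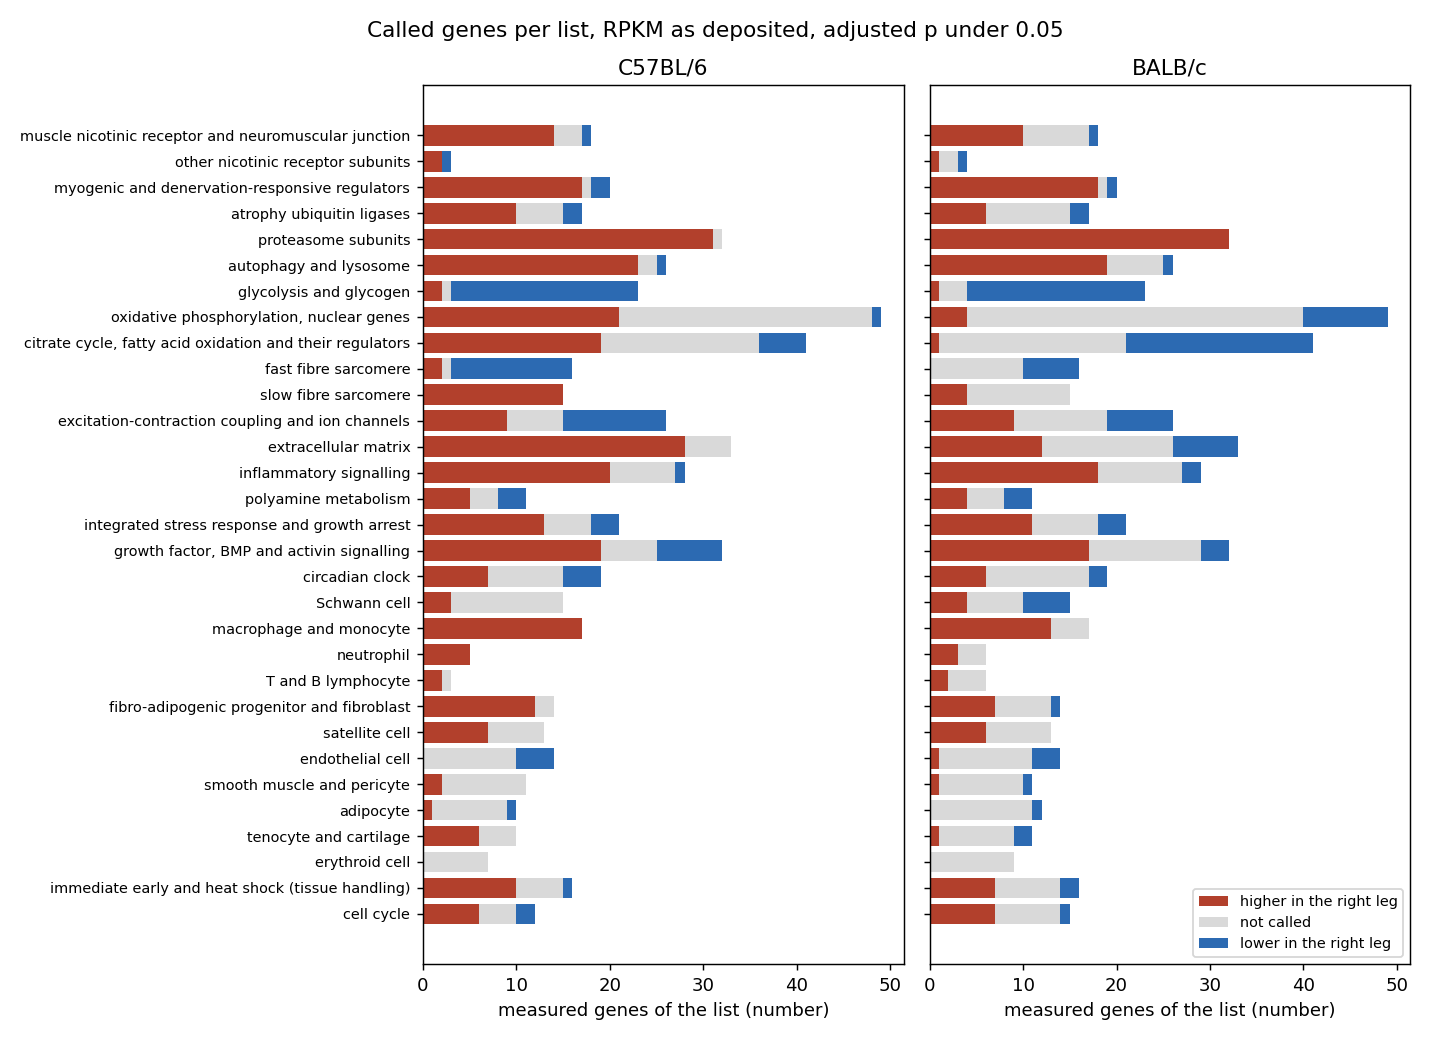
Bars give for each gene list the number of measured genes called higher, not called and called lower in the right leg (adjusted p under 0.05, RPKM as deposited), with C57BL/6 and BALB/c in separate panels and the number of genes on the horizontal axis. All 15 slow sarcomere genes rose in C57BL/6 and 4 in BALB/c, and proteasome subunits rose in both (31 and 32 of 32). In the C57BL/6 bars of oxidative phosphorylation, the citrate cycle and the atrophy ligases, more genes are higher than lower. The counts are 21 higher and 1 lower, 19 and 5, and 10 and 2. After median-of-ratios rescaling more of their genes are lower than higher (1 higher and 39 lower, 4 and 23, 2 and 10).

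In BALB/c, the comparison of the legs asked the same question. The receptor genes of fetal and denervated muscle rose. Chrng rose from 0.0577 ± 0.0769 to 102 ± 30.9 RPKM (log2 change 7.48 ± 0.23, relative 7.11, adjusted p = 1.7e-06). Chrna1 rose from 2.36 ± 0.853 to 191 ± 37.3 RPKM (relative log2 change 5.72) and Chrnd from 1.12 ± 0.735 to 165 ± 49.6 RPKM (relative log2 change 6.34). Musk rose from 2.24 ± 0.618 to 8.13 ± 0.387 RPKM (relative log2 change 1.30), and Ache fell from 14.5 ± 2.26 to 2.20 ± 0.727 RPKM (relative log2 change -2.88). Chrne was not called, with 10.5 ± 1.30 RPKM in the left and 6.08 ± 3.45 RPKM in the right legs (log2 change -0.85 ± 0.32, relative -1.23, adjusted p = 0.0544). It passed as lower after rescaling by median-of-ratios (adjusted p = 0.0176), to a common sum (0.0169) or by quantiles (0.0133). It also passed with the filter of 1 RPKM (0.0417), with limma-voom (0.0271) and without BALB/c right library 2 (0.00111). Of the 18 junction genes 10 rose and 1 fell (10 and 3 when adjusted over the list alone), and 7 rose and 4 fell after median-of-ratios rescaling (camera adjusted p = 0.414). Of 4 measured other nicotinic subunits 1 rose and 1 fell, also when adjusted over the list alone, and 0 rose and 1 fell after rescaling (camera adjusted p = 0.273). Chrna10 fell from 5.13 ± 0.811 to 2.50 ± 0.694 RPKM (relative log2 change -1.30), with an adjusted p of 0.0558 without both BALB/c libraries numbered 2, an alternative chosen after the data were seen. Chrnb2 rose from 0.0303 ± 0.0200 to 0.176 ± 0.0404 RPKM (log2 change 0.35, adjusted p = 0.0321). Its call ended after each rescaling (adjusted p up to 0.200 by quantiles), with eBayes without a trend (0.0504) and without BALB/c left library 1 (0.0788), left library 3 (0.0595) or right library 1 (0.0606).

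Myogenic and denervation-responsive regulators rose in BALB/c, 18 of 20 with 1 falling, also when adjusted over the list alone (camera adjusted p = 2.3e-06; adjusted p = 0.474 with an estimated correlation). Myog rose from 5.31 ± 1.23 to 156 ± 47.6 RPKM (log2 change 4.73 ± 0.24, relative 4.35, adjusted p = 1.2e-05). Gadd45a rose from 6.81 ± 1.81 to 773 ± 151 RPKM (relative log2 change 6.36) and Runx1 from 0.261 ± 0.00814 to 33.0 ± 3.40 RPKM (relative log2 change 5.08). Ncam1 rose from 1.96 ± 0.898 to 39.7 ± 9.40 RPKM (relative log2 change 3.71) and Myh3 from 4.73 ± 0.723 to 34.1 ± 16.1 RPKM (relative log2 change 2.26). The largest rises were those of Sln, from 9.30 ± 9.82 to 9478 ± 2304 RPKM (log2 change 10.48 ± 0.72, relative 10.10, adjusted p = 4.5e-05), and Krt18, from 0.236 ± 0.144 to 456 ± 188 RPKM (relative log2 change 8.82). They were followed by Aldh3a1 (relative log2 change 8.08), Rrad (relative log2 change 7.80) and Igfn1, a muscle Z-disc protein (relative log2 change 7.62). The largest fall was that of Dhrs7c, from 201 ± 35.8 to 3.16 ± 0.502 RPKM (log2 change -5.78 ± 0.18, relative -6.15, adjusted p = 1.6e-06). Mlf1 fell from 206 ± 33.0 to 7.07 ± 4.22 RPKM (relative log2 change -5.27). Kcng4, a potassium channel subunit, fell from 18.1 ± 2.71 to 0.325 ± 0.341 RPKM (relative log2 change -4.94). Perm1, a regulator of mitochondrial genes in muscle, fell from 53.0 ± 25.5 to 1.90 ± 1.26 RPKM (relative log2 change -4.88).

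Metabolic lists were lower than other genes in the right legs of BALB/c. Of 23 glycolysis and glycogen genes 19 fell and 1 rose (20 and 1 when adjusted over the list alone; camera adjusted p = 5.6e-19; adjusted p = 0.164 with an estimated correlation). Pfkm fell from 1198 ± 53.9 to 402 ± 39.4 RPKM (relative log2 change -1.95) and Gpd1 from 266 ± 30.5 to 23.8 ± 3.87 RPKM (relative log2 change -3.84). Of 49 oxidative phosphorylation genes 4 rose and 9 fell, and 0 rose and 25 fell after median-of-ratios rescaling (camera adjusted p = 9.6e-09; adjusted p = 0.728 with an estimated correlation). Without BALB/c right library 2, whose mean log2 level of this list was 8.06 against 7.43 and 7.48 in the other right libraries, 30 of these genes fell. Without right library 3, 5 fell, and without left library 3, 2 rose. Sdha, a subunit of complex II, fell from 164 ± 41.3 to 63.0 ± 3.29 RPKM (relative log2 change -1.72). Ndufs1, of complex I, fell from 96.5 ± 17.5 to 43.2 ± 9.21 RPKM (relative log2 change -1.53). Of 41 genes of the citrate cycle and fatty acid oxidation 20 fell and 1 rose, and 31 fell after rescaling (camera adjusted p = 3.3e-13; adjusted p = 0.728 with an estimated correlation). The mean log2 level of this list was 5.64, 6.36 and 5.69 in BALB/c left libraries 1, 2 and 3, and that of 10 adipocyte markers 2.37, 5.15 and 3.91. Without left library 2, 18 citrate cycle and fatty acid oxidation genes fell and 3 rose (camera adjusted p = 1.9e-11), and without both libraries numbered 2, 24 fell and 6 rose (1.2e-15). Idh2, mitochondrial isocitrate dehydrogenase, fell from 159 ± 74.1 to 36.3 ± 13.7 RPKM (relative log2 change -2.46) and Ppargc1a from 2.67 ± 0.608 to 1.16 ± 0.315 RPKM (relative log2 change -1.31). Of 11 polyamine genes 4 rose and 3 fell, and 3 rose and 5 fell after rescaling, with Amd1 falling from 38.4 ± 14.2 to 1.98 ± 0.575 RPKM (relative log2 change -4.30). The camera adjusted p of the polyamine list was 0.133, and 0.0249 without BALB/c left library 2. The counts of the last 3 lists were the same when adjusted over the list alone.

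Of the 16 fast sarcomere genes 6 fell and 0 rose in BALB/c (camera adjusted p = 2.3e-06; adjusted p = 0.681 with an estimated correlation). Mybpc2 fell from 1473 ± 228 to 93.6 ± 57.9 RPKM (relative log2 change -4.52) and Casq1, calsequestrin of fast fibres, from 2062 ± 479 to 609.5 ± 66.1 RPKM (relative log2 change -2.11). Without both BALB/c libraries numbered 2, 10 fast genes fell and 2 rose, and without left library 2 alone 6 fell and 2 rose. Of the 15 slow sarcomere genes 4 rose and 0 fell (camera adjusted p = 0.835), and 2 rose without BALB/c right library 2. Adjusted over the list alone, the fast and slow counts were the same. Csrp3 rose from 60.4 ± 31.8 to 807 ± 565 RPKM (log2 change 3.7 ± 0.57, relative 3.32, adjusted p = 0.00110). Tnnt1 rose from 232 ± 168 to 1390.0 ± 508 RPKM (log2 change 3.04 ± 0.77, relative 2.66, adjusted p = 0.0118), with an adjusted p of 0.0532 without BALB/c right library 2. It was at 38.6 RPKM in BALB/c left library 1 and at 337 and 320 RPKM in the other left libraries. Of 26 excitation-contraction coupling genes 9 rose and 7 fell (9 and 8 when adjusted over the list alone), and 7 rose and 12 fell after median-of-ratios rescaling. Kcnn3, a calcium-activated potassium channel, rose from 0.193 ± 0.0522 to 5.90 ± 1.29 RPKM (relative log2 change 2.81) and Kcna7, a voltage-gated potassium channel, fell from 32.2 ± 1.01 to 3.85 ± 0.984 RPKM (relative log2 change -3.31). The camera adjusted p of that list was 0.0312, lower than other genes (adjusted p = 0.728 with an estimated correlation). It was 0.0632 after rescaling, 0.0831 without BALB/c left library 1 and 0.0530 without left library 3.

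All 32 proteasome subunits rose in BALB/c, and 27 rose after median-of-ratios rescaling (camera adjusted p = 3.0e-09; adjusted p = 0.728 with an estimated correlation). Psmd4 rose from 99.6 ± 9.27 to 423 ± 57 RPKM (relative log2 change 1.70). Of 26 autophagy and lysosome genes 19 rose and 1 fell (20 and 1 when adjusted over the list alone), and 10 rose and 1 fell after rescaling. Map1lc3a rose from 109 ± 16.4 to 1287 ± 125 RPKM (relative log2 change 3.18). The camera adjusted p of the autophagy list was 0.00633 (adjusted p = 0.681 with an estimated correlation), and 0.0744 after rescaling. Of 17 atrophy ligases 6 rose and 2 fell, and 3 rose and 6 fell after rescaling (camera adjusted p = 0.727). The proteasome and ligase counts were the same when adjusted over the list alone. Trim63 rose from 74.1 ± 5.70 to 188 ± 42.1 RPKM (log2 change 1.32 ± 0.18, relative 0.94, adjusted p = 5.8e-04). Fbxo32 rose from 20.1 ± 2.05 to 42.9 ± 14.2 RPKM (log2 change 1.02 ± 0.25, relative 0.64, adjusted p = 0.0107). The call for Fbxo32 ended after each rescaling (adjusted p = 0.108 by median-of-ratios, 0.0678 to a common sum, 0.240 by quantiles), and it was 0.0517 without BALB/c right library 3.

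Matrix genes moved both ways in BALB/c. Of 33 measured, 12 rose and 7 fell, and 7 rose and 11 fell after median-of-ratios rescaling (camera adjusted p = 0.457). The 7 that fell became 2 without BALB/c left library 2, left library 3 or right library 3, 4 without right library 1 and 3 without right library 2. Col19a1, a minor collagen, rose from 0.149 ± 0.0521 to 17.8 ± 9.35 RPKM (relative log2 change 4.32). Tgfb1, transforming growth factor beta, rose from 6.22 ± 2.42 to 84.4 ± 17.2 RPKM (relative log2 change 3.33). Of the chains of type I collagen, Col1a1 (NM_007742, chromosome 11, 94797538 to 94814356) fell from 154 ± 30.4 to 90.0 ± 12.3 RPKM (log2 change -0.76 ± 0.19, relative -1.14, adjusted p = 0.010) and Col1a2 from 184 ± 32.8 to 98.8 ± 5.92 RPKM (relative log2 change -1.26). Without both BALB/c libraries numbered 2 the adjusted p of Col1a1 was 0.0728. Of 17 macrophage markers 13 rose (15 when adjusted over the list alone; camera adjusted p = 0.0116; adjusted p = 0.728 with an estimated correlation). The macrophage adjusted p was 0.0528 with the filter of 1 RPKM and 0.0613 without BALB/c right library 2. Tyrobp rose from 3.28 ± 0.264 to 15 ± 4.54 RPKM (relative log2 change 1.62) and C1qb from 9.98 ± 3.54 to 37.1 ± 12.9 RPKM (relative log2 change 1.46). Of 14 fibroblast markers 7 rose and 1 fell, and 2 rose and 3 fell after rescaling (camera adjusted p = 0.835). Without left library 1, left library 3 or right library 1, 3 of them rose, and 4 without right library 2. Of 11 tendon and cartilage markers 1 rose and 2 fell, and 1 rose and 8 fell after rescaling (camera adjusted p = 0.00634, lower; adjusted p = 0.728 with an estimated correlation). Without left library 1, 5 tendon markers fell, and 1 fell without left library 2 or 3 or right library 2 or 3. Scx, the 1 that rose, went from 5.78 ± 1.72 to 63.5 ± 19.4 RPKM (relative log2 change 2.96). Adjusted over the list alone, the matrix, fibroblast and tendon counts were the same.

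Of 15 Schwann cell markers 4 rose and 5 fell in BALB/c (4 and 6 when adjusted over the list alone), and 2 rose and 7 fell after median-of-ratios rescaling. Ngfr, a neurotrophin receptor, rose from 1.42 ± 0.266 to 7.42 ± 3.17 RPKM (relative log2 change 1.58). The list was lower than other genes (camera adjusted p = 0.0116; adjusted p = 0.728 with an estimated correlation). Without left library 1 or 3 or right library 1 or 3, 2 Schwann cell markers rose. The adjusted p of this list was 0.157 after rescaling, 0.270 with the filter of 1 RPKM and 0.0645 without both BALB/c libraries numbered 2. Of 14 endothelial markers 1 rose and 3 fell, and 0 rose and 11 fell after rescaling (camera adjusted p = 0.00124, lower; adjusted p = 0.728 with an estimated correlation). Kdr fell from 8.88 ± 3.74 to 3.07 ± 1.16 RPKM (relative log2 change -1.75). Of 12 adipocyte markers 1 fell and 0 rose (camera adjusted p = 0.0618). The adipocyte adjusted p was 3.1e-04 without BALB/c left library 1, 0.0128 without right library 2 and 0.0296 with the filter of 1 RPKM. Of 9 erythroid genes 0 were called by limma (camera adjusted p = 0.835), while without BALB/c right library 3 all 9 rose (camera adjusted p = 0.0199). The endothelial, adipocyte and erythroid counts were the same when adjusted over the list alone. Hba-a2, an alpha globin, was at 4523, 9566 and 123 RPKM in the right libraries. Its log2 change by limma was 2.74 ± 1.55 (adjusted p = 0.177, and 0.0102 without right library 3).

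In all, 14819 genes were tested in BALB/c. As deposited 6302 rose and 1136 fell (84.7% of the calls rose), against 3225 and 2818 after median-of-ratios rescaling (53.4% rose). Changes of at least 2-fold were called for 2765 genes that rose and 504 that fell. The deposited values of the legs did not overlap for 58.5% of the tested genes (10% by chance without a shift between the legs). With the median gene shifted by 0.38, this excess is no measure of how many genes changed either. Of the lists 4 were higher and 8 lower than other genes with the preset correlation, and 0 passed with an estimated correlation. The 10 most abundant genes held 28.6% to 36.0% of the reads of the left and 16.5% to 18.6% of those of the right libraries.

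Whether the strains responded alike was asked first by overlap. Over the 14165 genes tested in both tables, 5761 rose in both strains, where independent lists would share 3995. In the other direction 736 fell in both, where they would share 96.0. The odds ratios were 18.4 and 50.3, and the p-values of the one-sided Fisher's exact tests were too small for the test to return. After median-of-ratios rescaling 2442 rose in both (902 by chance) and 2093 fell in both (746). Across genes, which are not independent replicates, the changes correlated with Pearson's r of 0.83 and Spearman's rho of 0.78. The comparisons share no library. Genes that rose in one strain and fell in the other numbered 44 (risen in C57BL/6) and 19 (fallen in C57BL/6).

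**Figure D3:**
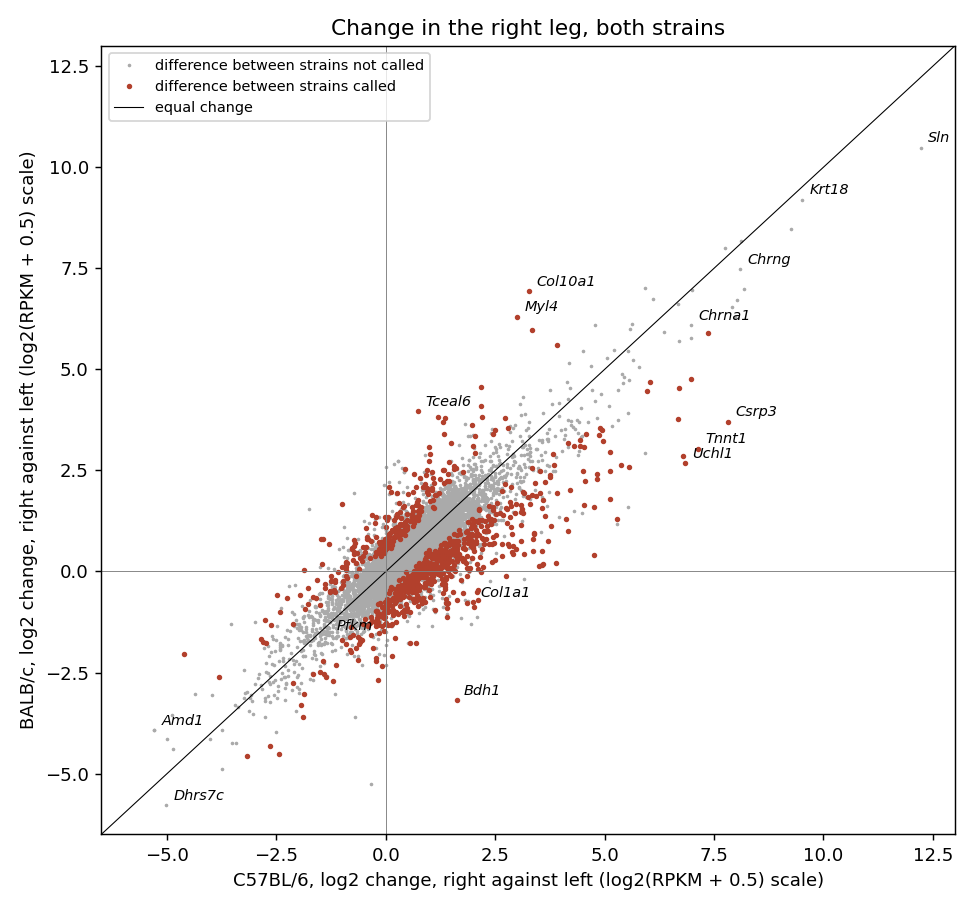
Each point is a gene tested in both strains, with its log2 change of right against left in C57BL/6 on the horizontal axis and in BALB/c on the vertical axis, where red points differ between the strains (adjusted p under 0.05) and the line marks equal change. Sln, Krt18, Chrng and Chrna1 lie at the upper right, Dhrs7c at the lower left, and Csrp3, Tnnt1 and Uchl1 below the line, with differences of -4.12, -4.09 and -4.16.

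The difference between the strains in the response was then tested gene by gene, as the BALB/c change minus the C57BL/6 change. Csrp3 rose from 7.02 ± 4.92 to 1546 ± 527 RPKM in C57BL/6 and from 60.4 ± 31.8 to 807 ± 565 RPKM in BALB/c (difference -4.12 ± 0.81, adjusted p = 0.0162). Uchl1, a ubiquitin hydrolase of neurons (NM_011670, chromosome 5, 67067360 to 67078473), had mean levels from left to right of 1.81 ± 0.364 to 263 ± 31.9 RPKM in C57BL/6 and 1.67 ± 1.23 to 13.1 ± 7.07 RPKM in BALB/c (difference -4.16 ± 0.63, adjusted p = 0.00498). Bdh1, an enzyme of ketone body use, went from 1.78 ± 0.790 to 6.96 ± 3.72 RPKM in C57BL/6 and from 13.2 ± 8.97 to 0.950 ± 1.02 RPKM in BALB/c (difference -4.81 ± 0.86, adjusted p = 0.0108). Myl4, an atrial and embryonic myosin light chain, had a higher change in BALB/c, from 6.26 ± 1.45 to 580.1 ± 284 RPKM against 17.7 ± 1.64 to 145 ± 13.9 RPKM in C57BL/6 (difference 3.30 ± 0.44, adjusted p = 0.00320). The transcript 2210011C24Rik also had a higher change (difference 2.67 ± 0.43, adjusted p = 0.00700). The tables were normalized separately, so levels are set side by side without a test, and they list another transcript for Bdh1, Tnnt1, Postn and Cd68.

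Other genes of the largest differences depended on the test or on single libraries. Col10a1, a collagen of growth cartilage that overlaps Nt5dc1, was at 0 in the C57BL/6 left libraries. It reached 4.87 ± 3.09 RPKM in the C57BL/6 and 66.9 ± 27.9 RPKM in the BALB/c right legs (difference 3.65 ± 0.50, adjusted p = 0.00327, and 0.504 with limma-voom). Ankrd55 reached 4.64 ± 0.562 and 37.4 ± 15.5 RPKM (difference 2.64 ± 0.34, adjusted p = 0.00268, and 0.808 with limma-voom). Tceal6 reached 0.379 ± 0.251 and 8.16 ± 1.45 RPKM (difference 3.24 ± 0.27, adjusted p = 2.3e-04, and 0.0528 with limma-voom). Spp1, osteopontin, went from 2.10 ± 3.55 to 33.8 ± 4.40 RPKM in C57BL/6 and from 1.40 ± 0.565 to 2.08 ± 0.913 RPKM in BALB/c (difference -4.34 ± 1.06, adjusted p = 0.0347). The difference for Tnnt1 was -4.09 ± 1.03, adjusted p = 0.0387. The calls for Spp1 and Tnnt1 held without C57BL/6 left library 1, BALB/c left library 1 or BALB/c right library 2. Without C57BL/6 left library 2, left library 3, right library 1, right library 2 and right library 3 in turn, the adjusted p of Spp1 was 0.0768, 0.0875, 0.0502, 0.0786 and 0.0838 and that of Tnnt1 0.0820, 0.0955, 0.0536, 0.0950 and 0.0764. Without BALB/c left library 2, left library 3, right library 1 and right library 3 it was 0.0722, 0.0726, 0.0664 and 0.0581 for Spp1 and 0.0889, 0.0795, 0.0647 and 0.0807 for Tnnt1.

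Among the lists, the slow sarcomere differed the most, with 9 of 15 genes lower in BALB/c (13 when adjusted over the list alone) and a median difference of -3.35. Its camera adjusted p was 2.9e-07 (adjusted p = 0.678 with an estimated correlation). Its mean log2 level in the left legs was 2.56 ± 0.24 in C57BL/6 and 6.34 ± 1.36 in BALB/c, and in the right legs 6.96 ± 0.48 and 7.66 ± 0.37, in tables normalized separately. Of 33 matrix genes 16 were lower (25 lower and 1 higher when adjusted over the list alone), with a median of -1.49 (camera adjusted p = 6.3e-09; adjusted p = 0.678 with an estimated correlation). Among them were Col1a1 (-2.75 ± 0.33, adjusted p = 0.00225), Col1a2 (-2.90 ± 0.35, adjusted p = 0.00225) and Postn (-3.33 ± 0.68, adjusted p = 0.0182). In the left legs, tendon and cartilage markers had a mean log2 level of 0.56 ± 0.31 in C57BL/6 and 3.73 ± 0.41 in BALB/c, and adipocyte markers one of 1.53 ± 0.49 and 3.81 ± 1.39. Of 41 citrate cycle and fatty acid oxidation genes 14 were lower (32 when adjusted over the list alone; camera adjusted p = 1.4e-11; adjusted p = 0.678 with an estimated correlation), and 9 after median-of-ratios rescaling. Of 49 oxidative phosphorylation genes 9 were lower (12 when adjusted over the list alone; camera adjusted p = 1.4e-05; adjusted p = 0.734 with an estimated correlation), and 3 after rescaling. These counts of lower genes depended on single libraries. With each library left out in turn they ranged from 3 (without C57BL/6 left library 3, right library 2 or 3, or BALB/c left library 2) to 15 (without BALB/c left library 1) for the slow sarcomere. For the matrix they ranged from 3 (without C57BL/6 right library 3) to 22 (without C57BL/6 right library 1 or BALB/c left library 1). For the citrate cycle list they ranged from 5 (without C57BL/6 left library 1, right library 2 or right library 3) to 23 (without BALB/c left library 1 or right library 2). For oxidative phosphorylation they ranged from 2 (without C57BL/6 right library 2 or 3) to 23 (without BALB/c right library 2).

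Further lists had lower changes in BALB/c, each with an adjusted p of 0.678 with an estimated correlation. They were tendon and cartilage (2 of 10 lower, 10 when adjusted over the list alone, camera adjusted p = 2.6e-04) and macrophage markers (3 of 17, 10 when adjusted over the list alone, 6.9e-04). Fibroblast markers (1 of 14, 7 when adjusted over the list alone, 0.00603) and the junction (2 of 18, 6 lower and 1 higher when adjusted over the list alone, 0.00322) were also lower. With each library left out in turn, the tendon count ranged from 0 (without C57BL/6 left library 1, left library 3 or right library 3) to 5 (without BALB/c left library 1). The macrophage count ranged from 1 (without C57BL/6 left library 1 or 3, right library 2 or 3, or BALB/c left library 2 or right library 3) to 7 (without BALB/c right library 2). The fibroblast count ranged from 0 (without C57BL/6 left library 1 or 2, or right library 2 or 3) to 4 (without C57BL/6 right library 1 or BALB/c left library 1). The junction count ranged from 0 (without C57BL/6 left library 3 or right library 2) to 5 (without BALB/c left library 1). The proteasome list was higher (1 of 32 genes, 0 when adjusted over the list alone, camera adjusted p = 2.7e-05; adjusted p = 0.678 with an estimated correlation). The lists of other nicotinic subunits, myogenic regulators, atrophy ligases, autophagy, glycolysis, Schwann cells, endothelium and adipocytes did not pass for the difference (camera adjusted p = 0.152, 0.956, 0.348, 0.205, 0.454, 0.563, 0.676 and 0.943). The Schwann cell list passed without C57BL/6 left library 1 (0.00299) and the glycolysis list without both BALB/c libraries numbered 2 (0.0187).

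Higher with a larger p, and again with an adjusted p of 0.678 with an estimated correlation, were 4 lists whose calls each ended without some library. The fast sarcomere had 2 genes higher and 2 lower of 16 (3 and 2 when adjusted over the list alone) and a camera adjusted p of 0.0230. It was 0.141 after median-of-ratios rescaling, 0.216 without BALB/c left library 2 and 0.105 without BALB/c right library 2. Excitation-contraction coupling had 3 higher and 3 lower of 26 (5 and 4 when adjusted over the list alone) and a camera adjusted p of 0.0262. It was 0.0544 with the filter of 1 RPKM, 0.0517 without C57BL/6 left library 1, 0.142 without BALB/c left library 2 and 0.123 without BALB/c right library 1. Of 11 polyamine genes 0 were called by limma (3 higher when adjusted over the list alone), with a camera adjusted p of 0.0398. The polyamine adjusted p was 0.0643 with the filter of 1 RPKM, 0.0580 after median-of-ratios rescaling, 0.0537 without C57BL/6 left library 3 and 0.0595 without C57BL/6 right library 1. It was 0.187 without BALB/c left library 2, 0.105 without BALB/c right library 2 and 0.0574 without BALB/c right library 3. Of 7 erythroid genes 0 were called by limma, also when adjusted over the list alone, with a camera adjusted p of 0.0235. The erythroid adjusted p was 0.141 after rescaling, 0.0566 without C57BL/6 left library 2, 0.0623 without C57BL/6 right library 1, 0.135 without BALB/c left library 3, 0.116 without BALB/c right library 1 and 0.294 without BALB/c right library 2.

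**Figure D4:**
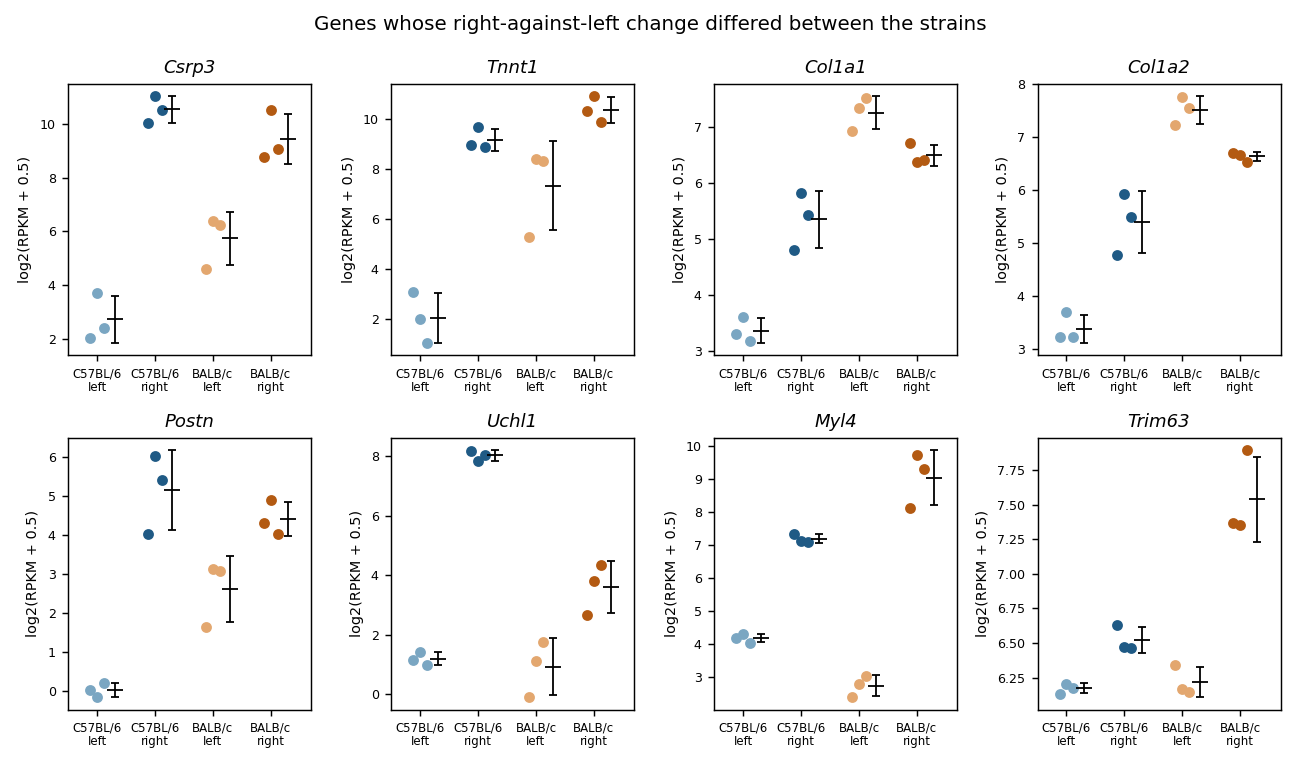
Each panel shows 1 gene with log2(RPKM + 0.5) per library on the vertical axis and the 4 groups on the horizontal axis, where points are libraries and bars the mean and SD of 3 libraries, from 2 tables normalized separately. Csrp3, Tnnt1, Col1a1, Col1a2, Postn and Uchl1 have a lower right-against-left change in BALB/c and Myl4 and Trim63 a higher one, with Trim63 differing by 0.97.

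In all, 14165 genes were tested for a difference between the strains. In BALB/c 249 had a higher and 613 a lower change (28.9% of the calls higher), against 555 and 521 after median-of-ratios rescaling (51.6% higher). The 862 calls became 415, 401 and 337 without C57BL/6 left libraries 1, 2 and 3, and 339 and 299 without C57BL/6 right libraries 2 and 3. They became 1303, 527 and 568 without BALB/c left libraries 1, 2 and 3. The higher calls alone moved to 505 without BALB/c right library 2 and to 164 without BALB/c right library 3.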

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

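Planned were the tests of genes and lists for the difference between the strains, the estimated correlation, leaving out each library and the splits. All other tests in this part, and the use of left-out libraries to weigh an explanation, were chosen only after the result was seen.

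The test of the difference between the strains gave 249 genes with a higher and 613 with a lower right-against-left change in BALB/c. After each gene's mean per strain was removed, strain labels were exchanged within each leg. Of 100 splits 1, the real one, gave as many as the 862 genes, and the highest of the other splits gave 84. The real split thus stood out among these splits. A real difference would widen the spread in the other splits, and the spread of the left libraries differed between the strains (dispersion 0.00373 in C57BL/6 and 0.0140 in BALB/c). Chance is therefore not excluded by these splits. Within C57BL/6, 1 of 10 splits of the 6 libraries, the real one, gave 10504 genes and the highest other gave 0. Within BALB/c, 1 of 10 gave 7438 and the highest other gave 1. These 10 splits are too few for a share under 0.05.

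The following genes differed between the strains by limma, as BALB/c minus C57BL/6 change. Higher in BALB/c were Col10a1 (3.65), Myl4 (3.30), Tceal6 (3.24), 2210011C24Rik (2.67), Ankrd55 (2.64), Asb2 (1.90), Trim63 (0.97), Map1lc3a (0.78) and Mdm2 (0.72). Lower in BALB/c were the sarcomere genes Csrp3 (-4.12), Tnnt1 (-4.09), Myh3 (-2.75), Myh2 (-2.66) and Myh1 (-2.28). Lower as well were the matrix and inflammatory genes Spp1 (-4.34), Postn (-3.33), Col1a2 (-2.90), Cd68 (-2.89), Col1a1 (-2.75) and Timp1 (-2.15). The metabolic genes Bdh1 (-4.81), Idh2 (-2.22), Perm1 (-2.06), Sdha (-1.13) and Ndufs1 (-1.11) were lower, as were Uchl1 (-4.16), Kcng4 (-1.39), Kcnn3 (-0.98) and Chrnb2 (-0.56). Their adjusted p ran from 2.3e-04 for Tceal6 to 0.0499 for Kcng4.

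These lists differed by camera with the preset correlation, given by their median difference, and 0 of them with an estimated correlation. Lower in BALB/c were slow sarcomere (-3.35), tendon and cartilage (-1.55), extracellular matrix (-1.49), citrate cycle and fatty acid oxidation (-0.90), fibroblast (-0.83), macrophage (-0.76), neuromuscular junction (-0.74) and oxidative phosphorylation (-0.48). Higher were erythroid cells (2.05), fast sarcomere (0.33), polyamine metabolism (0.32), proteasome (0.24) and excitation-contraction coupling (0.15).

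More genes rose than fell in both strains, and abundant transcripts that lost their share of the reads are a candidate explanation. Recomputed per read outside the 100 genes most abundant in the left legs, the median change went from 0.52 to -0.012 in C57BL/6 and from 0.38 to -0.072 in BALB/c. Those genes held 60.6% of the reads in the left and 34.1% in the right legs of C57BL/6, and 56.0% and 36.3% in BALB/c. Recomputing sets the remaining genes to a common total, which itself draws their median towards no change, so it is no independent test. The scaling totals of the right legs were 1.01 and 1.04 times those of the left, while the median gene was 1.44 and 1.30 times higher. RPKM values are already divided by these totals, so their ratio cannot test whether depth played a part. A general change of RNA content after denervation was not tested and stays open.

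The slow sarcomere list changed less in BALB/c, where its level in the left legs was higher. That level enters the difference between the changes, so it describes the result and is no separate explanation. The left legs of BALB/c were above those of C57BL/6 by 3.78 in mean log2 level and the right legs by 0.70, from tables normalized separately. The slow sarcomere list still passed camera at the preset correlation without each BALB/c left library (highest adjusted p 4.3e-06). Its estimated correlation was 0.673 (camera adjusted p = 0.678 with it), so that test cannot decide whether a single BALB/c left library was the cause. Whether the strains differ in fibre types or the pieces of muscle were taken from different parts was not tested, and both stay open.

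The matrix list also changed less in BALB/c, with a gap of 1.72 in the left and 0.32 in the right legs. The list still passed camera at the preset correlation without each BALB/c left library (highest adjusted p 1.8e-07). With an estimated correlation of 0.542 (adjusted p = 0.678 with it), that test cannot decide on a single library either. A lower share of muscle RNA was weighed by endothelial markers alone, whose gap the matrix gap exceeded by at least 0.905 in each BALB/c left library. Left gaps were 1.50 for fibroblast, 1.40 for macrophage and 2.28 for adipocyte markers, and 0.65 for endothelial and 0.42 for smooth muscle and pericyte markers. An equal gain of all other tissue is argued against as the whole cause, but a larger share of some tissues is not. More tendon in the BALB/c left samples could contribute, since tendon and cartilage markers outside the matrix list were higher there by 3.22, against 1.69 for the matrix genes outside the tendon list. It cannot be told apart from a difference between the strains, because every BALB/c left library lay above every C57BL/6 one.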

How the results depend on the processing

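The tests chosen only after the result was seen were limma-voom with and without median-of-ratios factors, the overlap with those factors and leaving out both BALB/c libraries numbered 2. In C57BL/6, 4106 genes rose and 3840 fell with median-of-ratios factors, 3798 and 4293 with quantiles, and 4116 and 3992 with limma-voom and median-of-ratios factors. With these settings Trim63 in C57BL/6 turned to -0.37, -0.28 and -0.37. With an absolute log2 change of at least 1, 3705 genes were called (3289 rose, 416 fell). In BALB/c, 3225 rose and 2818 fell with median-of-ratios factors, 3058 and 3050 with quantiles, and 3165 and 3113 with limma-voom and those factors. To a common sum 3948 rose, and with an absolute log2 change of at least 1, 3269 were called (2765 rose, 504 fell). For the difference between the strains the higher calls numbered 555 with median-of-ratios factors, 85 to a common sum, 422 with quantiles, 151 with limma-voom, 485 with limma-voom and median-of-ratios factors and 460 without both BALB/c libraries numbered 2. Genes in both strains became 2442 that rose and 2093 that fell with median-of-ratios factors. With an estimated inter-gene correlation 2 lists were called in C57BL/6 (0 higher, 2 lower), 0 in BALB/c (0 higher, 0 lower) and 0 for the difference (0 higher, 0 lower). With the filter of 1 RPKM 3 lists were higher in C57BL/6 and 3 for the difference, which was 2 with median-of-ratios factors and 3 without both BALB/c libraries numbered 2. With median-of-ratios factors the median log2 change of all genes was 0.021 in C57BL/6 and 0.016 in BALB/c, and the higher filter tests fewer genes. Whether these moved the counts was not tested, nor was the cause for the other settings.

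Leaving out each library in turn, 9690 to 10331 genes were called in C57BL/6 (rose 8577 to 9149, fell 1090 to 1182) and 5924 to 7830 in BALB/c (rose 5069 to 6770, fell 855 to 1083). The difference between the strains ranged from 299 (without C57BL/6 right library 3) to 1303 (without BALB/c left library 1). Its higher calls ranged from 80 (without C57BL/6 right library 3) to 505 (without BALB/c right library 2) and its lower calls from 219 to 1025 (without the libraries of the total). Fewer libraries enter each of these fits. Lists called ranged from 9 to 14 in C57BL/6 (higher 4 to 6, lower 5 to 8), 11 to 13 in BALB/c (higher 3 to 5, lower 7 to 9) and 10 to 13 for the difference (higher 2, without BALB/c left library 2, to 5, lower 8 to 9). Genes called in both strains ranged from 5324 to 6816 (rose 4728 to 6125, fell 596 to 734). Over single genes and libraries left out, 758 calls were the same, 30 were lost and 4 gained. Over lists 708 were the same, 24 lost and 12 gained. Where a list count of 3 or fewer genes moved by over 1.5 times without 1 library, it became at most 5, outside the lists whose counts are given with the results. The p of Chrna7 ranged from 0.36 to 1, and its depth of at most 3 reads limits any statement on it.

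With the replicate number as a block, 9144 genes rose and 1217 fell in C57BL/6, 5782 and 1058 in BALB/c, and 234 and 520 for the difference. In both strains 5290 rose and 715 fell. No count moved by over 1.5 times. In C57BL/6 the autophagy list was lost (0.0575) and the fibroblast list gained (0.0383), with Fbxo32 (0.0122) and Hbb-b1 (0.0445) gained and S100a9 lost (0.0507). In BALB/c Chrne (0.0286) and Hba-a2 (0.00972) were gained and Chrnb2 lost (0.0720). Of 12 libraries 9 correlated best with the library of their own number, with correlations of 0.0301 to 0.202, and 2 of 6 pairs were over 0.1. The BALB/c column codes skip the same number in both legs, but no label says that a number stands for a mouse. Whether the numbers pair the legs stays open, and the main tests did not pair them. Planned tests with edgeR and DESeq2 on recovered reads were not run, and limma-voom was the only test of those reads.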

Other observations

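The tests of the imprinted and interferon lists and of S100a9 against S100a8 were chosen only after the result was seen, as were the genes H19, Ifitm3 and Cdkn1c. Of the genes of growth factor, BMP and activin signalling, Mstn, myostatin, an inhibitor of muscle growth, fell from 26.1 ± 2.45 to 2.06 ± 0.174 RPKM in C57BL/6 (relative log2 change -3.90) and from 19.6 ± 7.66 to 1.40 ± 0.472 RPKM in BALB/c (relative log2 change -3.73). Gdf5, a BMP ligand, was at 0 in every C57BL/6 left library and at 11.2 ± 3.43 RPKM in the right legs, and rose in BALB/c to 23.0 ± 0.150 RPKM (relative log2 change 5.07). Fst, follistatin, rose in C57BL/6 to 14.5 ± 1.45 RPKM (relative log2 change 3.85). In C57BL/6, 19 of 32 rose and 7 fell, also when adjusted over the list alone (14 and 9 after median-of-ratios rescaling, camera adjusted p = 0.257). In BALB/c, 17 rose and 3 fell (17 and 4 when adjusted over the list alone, 13 and 9 after rescaling, 0.727), and 5 fell without right library 1. Of the immediate early and heat shock genes, Junb rose in C57BL/6 from 6.00 ± 1.40 to 65.7 ± 24.9 RPKM (relative log2 change 2.77) and Nr4a1 fell from 91.7 ± 22.7 to 13 ± 5.68 RPKM (relative log2 change -3.35). Of 16 of these genes 10 rose and 1 fell in C57BL/6 (7 and 2 after rescaling, 0.963) and 7 rose and 2 fell in BALB/c (3 and 2 after rescaling, 0.835), also when adjusted over the list alone. Without BALB/c left library 3 or right library 2 or 3, 4 of them rose and 1 fell in BALB/c, and 4 rose and 3 fell without left library 1.

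Inflammatory signalling genes rose in 20 of 28 with 1 falling in C57BL/6 (20 and 2 when adjusted over the list alone, camera adjusted p = 0.419, and 0.0278 after median-of-ratios rescaling with 16 and 6). That call was lost with an estimated correlation (adjusted p = 0.407). Tnfrsf12a, the TWEAK receptor, rose from 6.98 ± 1.88 to 88.6 ± 18.5 RPKM (relative log2 change 3.06). In BALB/c 18 of 29 rose and 2 fell, also when adjusted over the list alone (0.114, and 0.0211 after rescaling with 15 and 4; adjusted p = 0.540 with an estimated correlation). Of 21 genes of the integrated stress response and growth arrest 13 rose and 3 fell in C57BL/6 (12 and 5 after rescaling, 0.963) and 11 rose and 3 fell in BALB/c (8 and 4 after rescaling, 0.698), also when adjusted over the list alone. In BALB/c 1 of them fell without left library 3 or right library 1 or 3. Of 19 circadian clock genes 7 rose and 4 fell in C57BL/6, also when adjusted over the list alone (2 and 11 after rescaling). That list was lower than other genes (camera adjusted p = 0.0203; adjusted p = 0.250 with an estimated correlation). In BALB/c 6 rose and 2 fell (5 and 2 when adjusted over the list alone, 0 and 5 after rescaling, 0.222), and 3 rose without left library 1, 2 or 3 or right library 1 or 3.

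Of 13 satellite cell markers 7 rose in C57BL/6 (4 after rescaling, 0.577) and 6 in BALB/c (3 rose and 3 fell after rescaling, 0.835), also when adjusted over the list alone. Of 11 smooth muscle and pericyte markers 2 rose in C57BL/6 (1 rose and 6 fell after rescaling, 4 rose and 1 fell without left library 1, 0.0990) and 1 rose and 1 fell in BALB/c (0 and 4 after rescaling), also when adjusted over the list alone. The BALB/c adjusted p was 0.109, with 0.0458 with the filter of 1 RPKM and 0.0455 without right library 1. Of 12 cell cycle genes 6 rose and 2 fell in C57BL/6 (5 and 2 when adjusted over the list alone, 3 and 2 after rescaling, 0.555), and of 15 in BALB/c 7 rose and 1 fell, also when adjusted over the list alone (3 and 1 after rescaling, 0.727). Of 3 lymphocyte markers 2 rose in C57BL/6, also when adjusted over the list alone (0.886), and of 6 in BALB/c 2 (1 when adjusted over the list alone, 0.727). It was 1 without C57BL/6 left library 3, and 1 in BALB/c without left library 1, 2 or 3 or right library 1 or 2. Of 5 neutrophil markers 5 rose in C57BL/6 (2 after rescaling, 0.442) and of 6 in BALB/c 3 (3 after rescaling, 5 without right library 3, 0.457), also when adjusted over the list alone. For the difference between the strains, none of these 10 lists passed camera, with adjusted p from 0.205 to 0.943. The circadian list passed without BALB/c right library 2 (0.0220) and without both BALB/c libraries numbered 2 (0.0474), the latter chosen after the data were seen.

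Among the neutrophil genes, S100a8 rose from 0.182 ± 0.208 to 174 ± 95.4 RPKM in C57BL/6 (relative log2 change 7.39) and from 0.375 ± 0.157 to 139 ± 172 RPKM in BALB/c (relative log2 change 6.18). S100a9, its partner in neutrophils, was at 1.12 ± 0.886 RPKM in the right legs of C57BL/6 (adjusted p = 0.0327 by limma), which was 0.110 after median-of-ratios rescaling and 0.10, 0.110 and 0.0755 without left library 1, left library 2 or right library 2. Neutrophils in the right legs are a candidate source of S100a8. The levels argue against it, since S100a9 reached at most 4.10% of S100a8 in any right library and neutrophils hold both at like levels.

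H19, an imprinted long non-coding RNA, rose from 164 ± 23.2 to 3575 ± 937 RPKM in C57BL/6 (relative log2 change 3.89) and from 282 ± 94.3 to 2310.5 ± 1090.5 RPKM in BALB/c (2.60). Cdkn1c, another imprinted gene, rose from 21.5 ± 5.44 to 102 ± 42.3 RPKM (1.65) and from 16.0 ± 3.91 to 280 ± 63.7 RPKM (3.72). A rise of imprinted growth-related genes as a group was a hypothesis. Of 17, 9 rose and 1 fell in C57BL/6 and 5 rose and 2 fell in BALB/c. The unadjusted camera values, over all tested genes, were 0.777 (direction up) and 0.683 (direction down). In BALB/c the median log2 change of the list was 0.23, below the 0.38 of all genes, so the values there do not point to a joint rise, and the hypothesis stays open. Ifitm3, an interferon-induced membrane protein, rose from 40.4 ± 4.42 to 1649.8 ± 402 RPKM in C57BL/6 (4.79) and from 62.9 ± 9.38 to 1563 ± 752 RPKM in BALB/c (4.11). A joint rise of interferon-induced genes was tested likewise. Of 20 measured 13 rose in C57BL/6 and of 19 measured 13 rose in BALB/c, with 0 falling. Of all tested genes, 9258 of 14551 rose in C57BL/6 and 6302 of 14819 in BALB/c. The unadjusted camera values were 0.731 and 0.113, which leaves it open too.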
